A study of Mus musculus with 12 samples.

How the data were processed

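Transcript levels were measured in dermal fibroblasts of 2-day-old mice. Per the labels' protocols, the skin was dissected, the layer under the dermis was removed, and the rest was digested with collagenase. Cells that carried Pdgfra and CD34 and none of CD45, CD117, CD31 or EpCam were then sorted by flow cytometry, per the labels' protocols. The CD26+ papillary gate took cells without Dlk1 or Sca1 at the surface. The Dlk1+ reticular gate took cells without CD26 or Sca1. The Dlk1+ Sca1+ and Dlk1− Sca1+ gates, both named pre-adipogenic in the labels, took cells without CD26. RNA of 4500 cells per sample was isolated on magnetic beads and amplified over 21 cycles, and 8 µg of cDNA were fragmented and labelled with biotin for an Affymetrix array, per the labels' protocols. Amplification over many cycles can compress or distort differences between transcripts, and RMA values of dim probe sets understate fold differences.

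The authors deposited 1 table of log2 expression values for 12 arrays, rounded to 2 decimals. The values were made by RMA with the affy package, per the submitters' processing notes, and their versions were not given in the sources used here. RMA corrects the background, normalizes the arrays to a common distribution by quantiles and summarizes the probes of each probe set. The deposited log2 values ran from 3.30 to 13.27, and the sorted columns differed from each other by at most 0.17, and no further normalization was applied. A genome build was not given in the sources used here, and no coordinates are printed. Array medians were 6.21 to 6.34. For arrays, precision is limited by their number, which was 3 per population.

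The table held 45141 probe sets, of which 104 were array controls and were left out. A platform annotation table paired 28898 probe sets with 1 gene symbol and 551 with several. The other 15588, or 34.61% of the probe sets that were not controls, are unnamed here and entered no gene count. Symbols were updated through Entrez numbers, of which those of 28689 probe sets matched a RefSeq gene, and 0 symbols changed. For each gene, the probe set with the highest mean over the 12 arrays was taken, among probe sets with 1 symbol, which left 17097 genes. No filter on dim genes was used. In 278 pairs of a named gene and a comparison with more than 1 probe set, 1 pair had a probe set called in the opposite direction. In some pairs not all probe sets were called. Examples in papillary against reticular cells are Cebpb (1 of 3), Car3 (1 of 4) and H2-D1 (1 of 5).

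Each array was assigned to its population and animal from its label. All 12 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with a coefficient per population, 8 residual degrees of freedom and 4.475 prior degrees of freedom from empirical Bayes moderation. All 6 pairs of populations were contrasted, and p-values were adjusted by Benjamini-Hochberg within each contrast. A gene was called at an adjusted p under 0.05. A moderated F-test over the 4 populations was adjusted the same way. A gene counted as highest in a population when it was called higher there in each of the 3 contrasts with the others. Differences in the text are log2 differences of means with limma's standard error (SE), and levels are log2 RMA means with the SD over 3 animals.

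A set of 27 gene lists on fibroblast types, adipogenesis, signalling, matrix, cell state and other cell types was fixed from textbook knowledge, with the sorting genes kept apart. Each list was tested in each contrast with limma's camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg over the 162 tests. Camera with a correlation estimated from the data and fry, a test of a list on its own, were run beside it. Counts of members were taken over all genes tested and adjusted over the list alone. The position of the Dlk1+ Sca1+ population between Dlk1+ reticular and Dlk1− Sca1+ was computed in each animal in turn, over genes that separated the outer populations at an unadjusted p under 0.01 in the other 2 animals, as the mean signed difference from reticular divided by that of Dlk1− Sca1+.

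The lists, the rule for named genes and the settings named below, except where said otherwise, were chosen before the data were examined. The rule takes the sorting genes, per contrast and direction the 10 called genes with the largest difference whose 3 values in one population all lie above the 3 in the other, up to 4 called members per list by size of the difference, and the 10 genes per population with the largest smallest difference from the other 3. Genes known by a clone or model name were left out.

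The labels give 3 littermates and a replicate number from 1 to 3 for each array, and arrays with the same number were taken as from the same animal. Deviations from the population means correlated between arrays of the same animal with a mean r of 0.266 (range 0.086 to 0.432, 17 of 18 pairs above 0.1). These correlations are across genes, which are not independent replicates. The labels give replicate numbers and no statistical model. The model without an animal term was kept as chosen beforehand, and a fit with the animal as a block (6 residual degrees of freedom) was run beside it.

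Other settings run were an intensity trend with robust moderation, leaving out genes below a mean log2 of 6.28, the median over probe sets (10009 genes stayed), the mean of a gene's probe sets, every probe set on its own, centring or repeated quantile normalization of the arrays, array weights, a fit on the compared arrays alone, a 2-fold minimum, a stricter p for the position genes, and leaving out each array or animal. A covariate of keratinocyte marker levels, and leaving out 3 arrays with high markers of other cell types together, were chosen after seeing the data. The fits and list tests were tested on simulated data with 200 changed genes among the 17097, drawn for the contrast of papillary and reticular arrays. They recovered 63% of genes changed by 0.5 log2, 98.5% at 1 log2 and 100% at 2 log2, with 4, 12 and 15 false calls. Between 2 unchanged populations 0, 1 and 0 lists were called. The simulated noise was independent between genes and arrays, so this does not cover shared animals or correlated genes of a list.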

Results

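Fibroblasts of the skin of 3 female littermates aged 2 days were sorted into 4 populations, and each was measured on 1 array per animal. The populations were CD26+ papillary, Dlk1+ reticular, Dlk1+ Sca1+ and Dlk1− Sca1+ cells. Differences below are log2 differences of the first population minus the second, with limma's SE and n = 3 animals per population. Levels are log2 means with the SD over animals. The number of arrays limits the precision of each value.

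The transcripts of the sorting markers were read first, as a check of the labels. Dpp4, which encodes CD26, was at 10.61 ± 0.40 in papillary cells and at 6.30 ± 0.22, 6.26 ± 0.06 and 6.37 ± 0.20 in reticular, Dlk1+ Sca1+ and Dlk1− Sca1+ cells. The papillary minus reticular difference was 4.32 ± 0.17, a 19.9-fold difference (adjusted p = 1.64e-09). Dlk1, an imprinted gene for a membrane protein that restrains adipocyte formation, was at 12.97 ± 0.07 in reticular and 12.86 ± 0.04 in Dlk1+ Sca1+ cells, with a difference between these of -0.10 ± 0.10 (adjusted p = 0.725). It was at 11.39 ± 0.19 in Dlk1− Sca1+ cells, -1.47 ± 0.10 from Dlk1+ Sca1+ cells (adjusted p = 2.49e-06), and at 9.97 ± 0.14 in papillary cells. The Dlk1 transcript was thus well above the low end of the scale in both populations sorted as Dlk1 negative. Cd34 was at 10.34 in Dlk1+ Sca1+ cells and 10.01 in papillary cells, and differed by -0.34 ± 0.10 between Dlk1− Sca1+ and Dlk1+ Sca1+ cells (adjusted p = 0.0503, or 0.0435 with the animal as a block). Pdgfra was at 7.64, 7.07, 7.10 and 7.25 in the order papillary, reticular, Dlk1+ Sca1+ and Dlk1− Sca1+. It passed in no comparison, and with the animal as a block its adjusted p was 0.0265 for papillary against reticular and 0.0339 for papillary against Dlk1+ Sca1+. The transcripts of the markers sorted against were low for Ptprc (3.88 to 3.94) and Kit (4.39 to 4.88), with an adjusted p of 0.0596 for Kit in papillary against Dlk1+ Sca1+ cells, or 0.0443 with the block. Pecam1, also sorted against, was not low, at 7.02, 7.71, 8.15 and 7.68 in the order papillary, reticular, Dlk1+ Sca1+ and Dlk1− Sca1+. It reached 8.74 in the Dlk1+ Sca1+ array of animal 2. Pecam1 was lower in papillary than in Dlk1+ Sca1+ cells by -1.13 ± 0.22 (adjusted p = 0.00145). Epcam reached 8.62 in the Dlk1− Sca1+ array of animal 1 and had a mean of 6.89 ± 1.5 in that population. The Sca1 transcript was not analysed here.

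**Figure D1:**
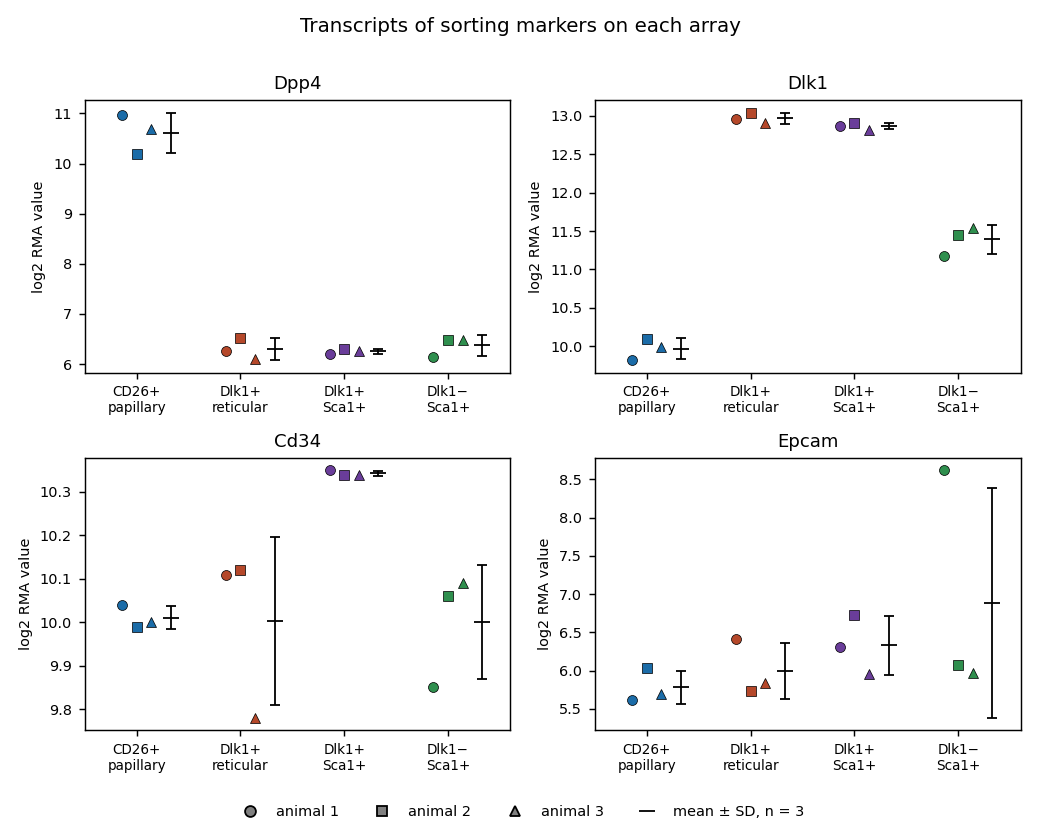
Log2 levels of Dpp4, Dlk1, Cd34 and Epcam in each array, with the mean and SD of each population (n = 3 animals).

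Papillary cells stood apart from the other 3 populations. Correlations between arrays were 0.989 to 0.995 within a population, 0.948 to 0.962 between papillary and other arrays, and 0.971 to 0.99 among the other 3 populations. The first principal component took 57.7% of the variance and set papillary arrays apart, and the second took 17.9% and ordered the rest as reticular, Dlk1+ Sca1+ and Dlk1− Sca1+. The moderated F-test passed 6100 of 17097 genes (35.7%), 4056 and 3949 without animal 2 and animal 3. Papillary cells had 1363 genes higher than in each other population (7.97%), reticular cells 317 (1.85%), Dlk1− Sca1+ cells 264 (1.54%) and Dlk1+ Sca1+ cells 99 (0.579%). With the animal as a block the last 2 counts were 424 and 169. Without animal 2 and animal 3 the reticular count was 125 and 119, and it was 207 without Dlk1+ Sca1+ replicate 3. Without animals 1, 2 and 3 the Dlk1− Sca1+ count was 149, 129 and 101 and the Dlk1+ Sca1+ count was 48, 52 and 26. The Dlk1+ Sca1+ count was 61 and 60 without its own replicates 1 and 3.

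**Figure D2:**
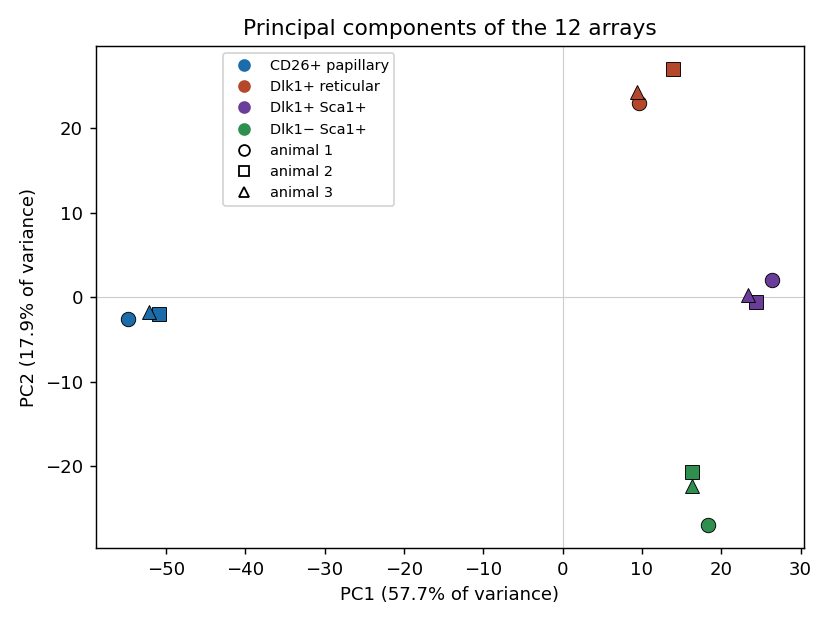
First 2 principal components of the 12 arrays over all genes tested, with colour for population and shape for animal.

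Each population had genes that were higher in it than in the other 3. For papillary cells the smallest of the 3 differences was 4.64 for Chodl, a membrane lectin, 4.45 for Grem1, a secreted antagonist of BMPs, and 4.53 and 3.96 for the atypical chemokine receptors Ackr4 and Ackr3. The basement membrane collagen gene Col4a6 (3.40) and the growth factor receptor gene Fgfr4 (3.36) followed. For reticular cells it was 2.72 for Thbs4, a matrix thrombospondin, 2.33 for Mgp, an inhibitor of calcification, 1.87 for Nppc, which encodes C-type natriuretic peptide, and 1.71 for Smoc1. Dlk1− Sca1+ cells had Sema3g, a secreted semaphorin (2.35), the water channel gene Aqp1 (2.13), the metalloprotease gene Adamts18 (1.95), the angiopoietin receptor gene Tek (1.64) and the conjugating enzymes Ugt1a9 (2.07) and Ugt1a6a (1.87), which share exons and are not independent. Dlk1+ Sca1+ cells had smaller values, with Akr1c14 at 1.60, Fgf23 at 1.23, Met at 1.09 and the similar genes Ifi203, Ifi205 and Ifi204 at 1.80, 1.54 and 1.38. These 3 are close relatives and are not counted as independent.

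**Figure D3:**
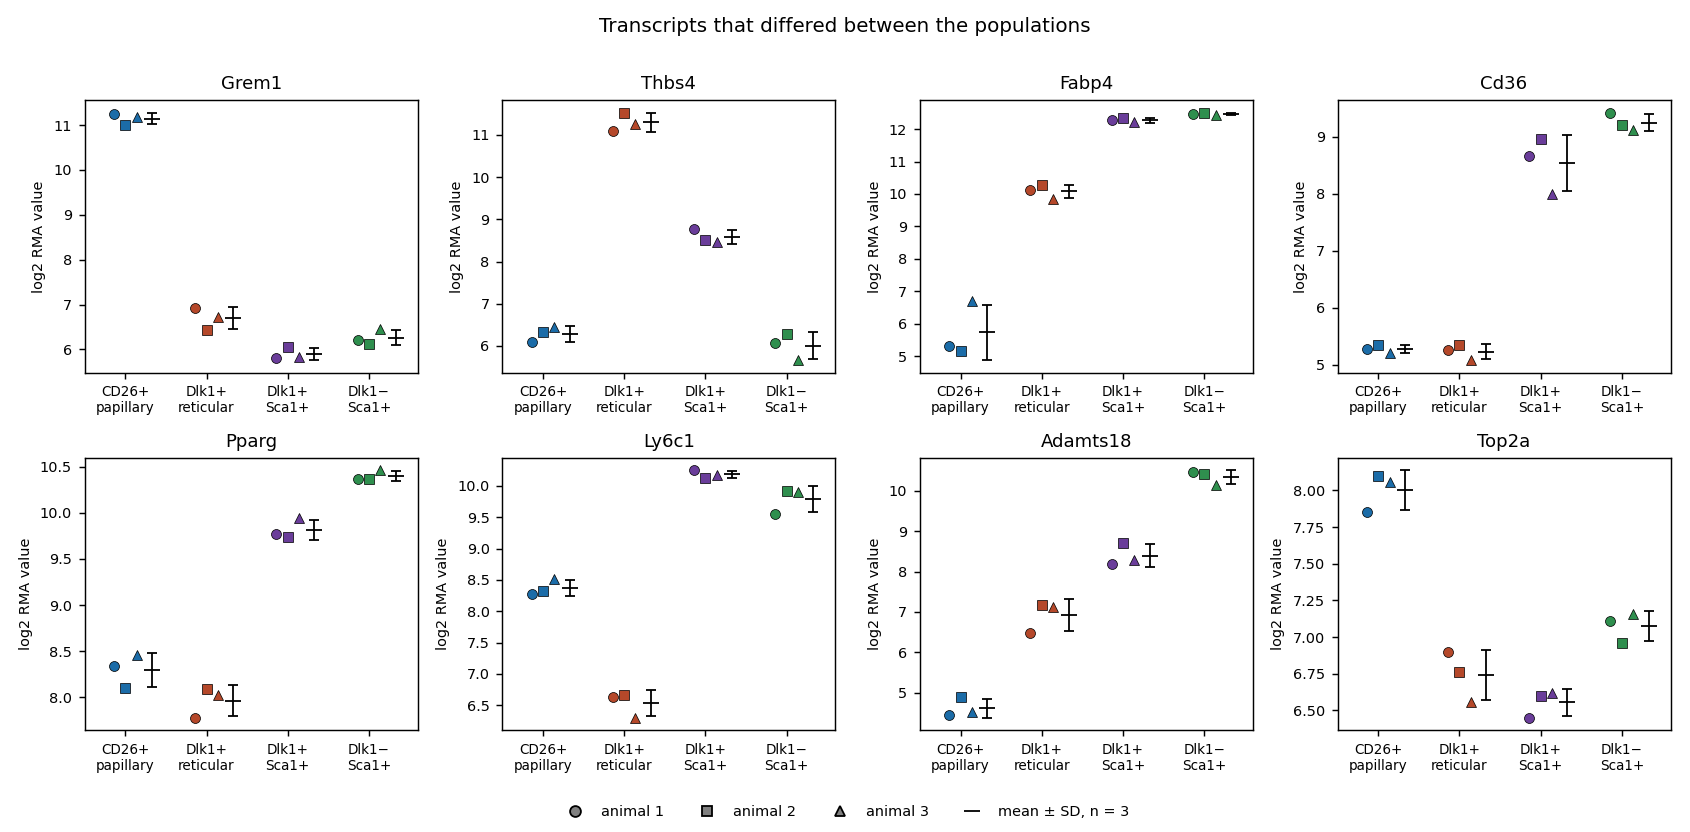
Log2 levels of 8 genes in each array of the 4 populations, with the mean of each population.

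The 27 gene lists were tested with limma's camera at a preset correlation, and the adjusted p given for a list below is from that test after Benjamini-Hochberg over 162 tests. These list calls are weak. When the 6 arrays of a comparison were split in other ways, up to 14 lists passed, against 12 to 18 in the real comparisons. Each other split mixed the populations unevenly and kept part of their difference, so these counts do not measure chance. With a correlation estimated from the data, 12 of the 87 calls passed, and each of these is named below. These calls are not independent, since some lists share genes. Apcdd1, Wif1, Rspo1 and Nkd2 are in both the papillary and the Wnt list. Wnt2 is in the Wnt and the fascia and adventitia lists, and Inhba in the TGF-beta and BMP and the dermal papilla lists. Members were counted as higher, lower or not past the threshold over all genes, and then adjusted over the list alone. The immune, mast cell, erythroid and melanocyte lists passed in none of the 6 comparisons, with 0.0503 as the smallest adjusted p for immune genes and 0.0567 for melanocyte and Schwann genes.

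**Figure D4:**
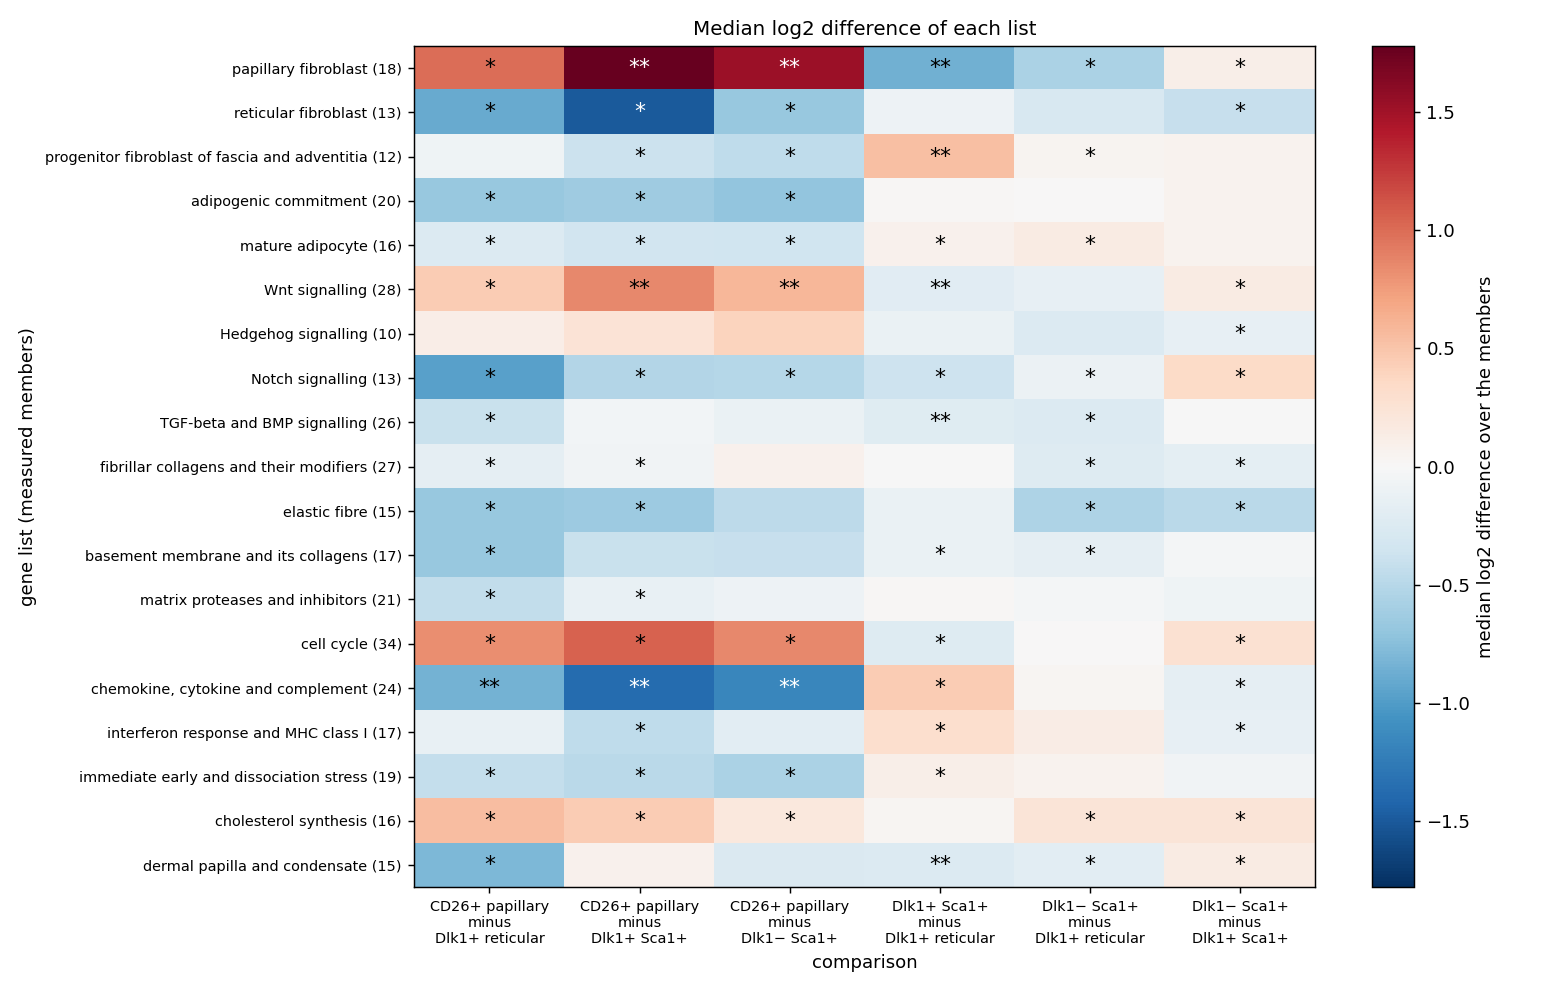
Median log2 difference of the members of 19 gene lists in the 6 comparisons. A single asterisk marks an adjusted p under 0.05 in camera at the preset correlation, and 2 asterisks mark that it was also under 0.05 with an estimated correlation.

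In papillary against reticular cells, Grem1 was higher by 4.45 ± 0.13, a 21.9-fold difference, Chodl by 4.64 ± 0.24 and Ackr4 by 4.53 ± 0.21. The transcription factor gene Maf was higher by 3.57 ± 0.08. Agtr2, a receptor for angiotensin II, was at -6.42 ± 0.11, an 85.4-fold difference, and Gfra1, a co-receptor for the neurotrophic factor GDNF, at -6.34 ± 0.22. Angptl1 was at -5.58 ± 0.13, Plat, which encodes tissue plasminogen activator, at -5.03 ± 0.10, Thbs4 at -5.01 ± 0.16 and Lgr5, a receptor for R-spondins, at -4.63 ± 0.14.

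Of 34 measured cell cycle genes, 29 were higher in papillary than in reticular cells, 1 was lower and 4 did not pass (30 and 1 over the list alone), among them Ccna2 (1.49), Nusap1 (1.39) and Aurkb (1.36). The list had an adjusted p = 1.74e-13 (adjusted p = 0.127 with an estimated correlation). Of 24 chemokine, cytokine and complement genes none were higher and 17 were lower (20 over the list alone), with C1s1 at -4.58, Ccl7 at -3.05 and Cxcl12 at -2.92. That list passed at adjusted p = 5.03e-12 and with an estimated correlation at 0.0363. Notch pathway genes were lower in 10 of 13 cases (11 over the list alone), with Heyl at -4.28, Jag1 at -2.54 and Notch3 at -1.80 (adjusted p = 9.21e-09, and adjusted p = 0.0753 with an estimated correlation). Pericyte and smooth muscle genes, a list that shares Notch3, moved the same way, with 6 of 13 lower and none higher (9 lower and 2 higher over the list alone), among them Kcnj8 (-3.37) and Acta2 (-1.83), at adjusted p = 0.000375 (adjusted p = 0.0816 with an estimated correlation). Notch3 and Heyl are also genes of mural cells. Of 20 genes of adipogenic commitment 13 were lower, 1 was higher and 6 did not pass (13 and 2 over the list alone), including Zfp423 (-2.59), Ebf2 (-2.56) and Cebpb (-1.87), at adjusted p = 2.19e-06 (adjusted p = 0.0816 with an estimated correlation). Elastic fibre genes were lower in 9 of 15 cases and higher in 1 (9 and 2 over the list alone), led by Mfap5 (-3.76) and Ltbp2 (-3.12), at adjusted p = 9.11e-05 (adjusted p = 0.0816 with an estimated correlation).

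Genes on the papillary list were higher in papillary than in reticular cells in 12 of 18 cases and lower in 3 (13 and 3 over the list alone). Sema3a (2.17), Rspo1 (2.12) and Entpd1 (1.86) were among them, at adjusted p = 4.78e-05 (adjusted p = 0.0568 with an estimated correlation). The Wnt list moved up by its median of 0.46, with 15 of 28 genes higher and 3 lower (16 and 4 over the list alone), at adjusted p = 0.00237 (adjusted p = 0.0576 with an estimated correlation). It holds both activators and inhibitors, and the receptors Lgr5 (-4.63) and Fzd4 (-4.16) moved against the list while Axin2, a target gene, was higher by 2.01. In the skeletal muscle list 6 of 13 genes were lower and 1 was higher (7 and 1 over the list alone), with Acta1 at -3.04 and Tnnc2 at -2.70, at adjusted p = 0.00978 (adjusted p = 0.194 with an estimated correlation). In all, 4702 genes passed (27.5%), 2375 higher and 2327 lower in papillary cells, and 18 lists passed. The even split depended on scaling, since with arrays centred on their medians 2848 were higher and 2060 lower. The muscle and pericyte markers could not be assigned to fibroblasts from these arrays.

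Against Dlk1+ Sca1+ cells, papillary cells had higher Col26a1, a collagen gene (5.60 ± 0.15, 48.4-fold), Chodl (5.42 ± 0.24) and Grem1 (5.25 ± 0.13). The transcription factor gene Trps1 was higher by 4.28 ± 0.16. Agtr2 was at -6.68 ± 0.11, a 103-fold difference, and Fabp4, which encodes the fatty-acid-binding protein of adipocytes, at -6.55 ± 0.29, a 93.9-fold difference. Lgr5 was at -5.51 ± 0.14, Plat at -5.38 ± 0.10 and the cytochrome P450 gene Cyp1b1 at -5.14 ± 0.13.

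Cell cycle genes were higher in papillary than in Dlk1+ Sca1+ cells in 28 of 34 cases and lower in 1 (29 and 1 over the list alone), as for Cenpf (1.90) and Ccna2 (1.84), at adjusted p = 3.44e-15 (adjusted p = 0.108 with an estimated correlation). With an estimated correlation 3 lists passed as well. Chemokine, cytokine and complement genes were lower in 19 of 24 cases and higher in none (20 over the list alone), with C1s1 at -5.26 and Ccl7 at -4.37 (adjusted p = 1.33e-14, estimated 0.0288). Papillary list genes were higher in 12 of 18 cases and lower in 1 (13 and 1 over the list alone), with Entpd1 (3.95) and Apcdd1 (3.05) among them (adjusted p = 1.02e-09, estimated 0.0209). Wnt genes were higher in 17 of 28 cases and lower in 3 (18 and 4 over the list alone), with Rspo3 at 3.46, while Lgr5 (-5.51) and Fzd4 (-5.11) moved the other way (adjusted p = 8.4e-06, estimated 0.0209).

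Mature adipocyte genes were lower in papillary than in Dlk1+ Sca1+ cells in 7 of 16 cases and higher in none (10 over the list alone). Besides Fabp4 these were Cd36, a scavenger receptor for fatty acids (-3.26), Car3 (-3.15) and the lipase gene Lpl (-3.08), at adjusted p = 0.000109 (adjusted p = 0.0636 with an estimated correlation). Fabp4 and Cd36 are also genes of capillary endothelium, and endothelial genes were lower in 5 of 16 cases and higher in none (5 over the list alone), with Tek at -2.85, at adjusted p = 0.0126 (adjusted p = 0.291 with an estimated correlation). Tek did not follow its list between the Sca1+ populations. It was at 8.13 ± 0.09 in Dlk1+ Sca1+ and 9.77 ± 0.09 in Dlk1− Sca1+ cells, where the list as a whole was lower. Genes of adipogenic commitment were lower in 14 of 20 cases and higher in 3 (14 and 3 over the list alone), with Cebpd at -2.64 and Zfp423 at -2.62, at adjusted p = 3.29e-06 (adjusted p = 0.0816 with an estimated correlation). In all, 4787 genes passed (28%), 2411 higher and 2376 lower in papillary cells (2480 and 2531 after repeated quantile normalization), and 16 lists passed.

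Against Dlk1− Sca1+ cells, papillary cells again had higher Chodl (5.42 ± 0.24), Grem1 (4.88 ± 0.13, 29.5-fold) and Col26a1 (4.65 ± 0.15). Fabp4 was at -6.74 ± 0.29, a 107-fold difference, Cyp1b1 at -6.44 ± 0.13, an 87-fold difference, and Adamts18 at -5.73 ± 0.19. The secreted BMP regulator Bmper was at -4.85 ± 0.14 and the Wnt receptor gene Fzd4 at -4.93 ± 0.13.

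Cell cycle genes were higher in papillary than in Dlk1− Sca1+ cells in 27 of 34 cases and lower in 1 (28 and 1 over the list alone), with Ccna2 at 1.56 and Kif11 at 1.44 (adjusted p = 2.22e-13, and adjusted p = 0.127 with an estimated correlation). Here too, 3 lists passed with an estimated correlation. They were chemokine, cytokine and complement genes, lower in 16 of 24 cases and higher in none (18 over the list alone, Cxcl12 -3.86, adjusted p = 2.66e-12, estimated 0.0363), papillary genes, higher in 14 of 18 and lower in 1 (14 and 1 over the list alone, Tnfrsf19 2.80, adjusted p = 5e-09, estimated 0.0209), and Wnt genes, higher in 16 of 28 and lower in 4 (16 and 4 over the list alone, Dkk2 3.18, adjusted p = 0.000268, estimated 0.0363). Mature adipocyte genes were lower in 7 of 16 cases and higher in none (7 over the list alone), with Cd36 at -3.97 and Lpl at -3.06, at adjusted p = 2.09e-05 (adjusted p = 0.0518 with an estimated correlation). Pparg, the main transcription factor of adipocytes, was at -2.10 in the commitment list, of which 13 of 20 genes were lower and 3 higher (13 and 3 over the list alone, adjusted p = 1.4e-06, and adjusted p = 0.0816 with an estimated correlation). In all, 4508 genes passed (26.4%), 2235 higher and 2273 lower in papillary cells (2349 and 2232 with arrays centred), and 12 lists passed. With the animal as a block, interferon genes (adjusted p = 0.0503, or 0.0347) and melanocyte and Schwann genes (adjusted p = 0.0567, or 0.0362) passed as well.

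Dlk1+ Sca1+ cells differed from reticular cells in fewer genes than papillary cells did. Ly6c1, a member of the Ly6 family of similar surface proteins, was higher by 3.65 ± 0.12, a 12.6-fold difference. Cd36 was higher by 3.31 ± 0.18, a 9.89-fold difference, Bmper by 3.23 ± 0.14, the fibulin gene Efemp1 by 2.40 ± 0.16 and Fabp4 by 2.20 ± 0.29. Col26a1 was at -3.59 ± 0.15, Trps1 at -2.77 ± 0.16, Thbs4 at -2.72 ± 0.16 and Inhba, which encodes an activin subunit, at -2.66 ± 0.25.

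With an estimated correlation 5 lists passed in Dlk1+ Sca1+ against reticular cells. Papillary list genes were lower in 12 of 18 cases and higher in 1 (12 and 3 over the list alone), with Trps1 at -2.77 and Entpd1 at -2.09 (adjusted p = 5e-09, estimated 0.0209). Genes of TGF-beta and BMP signalling were lower in 11 of 26 cases and higher in none (11 over the list alone), with Inhba at -2.66 and Bmp4 at -1.36 (adjusted p = 6.5e-07, estimated 0.043). Fascia and adventitia genes were higher in 7 of 12 cases and lower in none (8 over the list alone, adjusted p = 1.92e-06, estimated 0.0288), led by Ly6c1. Dermal papilla genes were lower in 7 of 15 cases and higher in 1 (7 and 1 over the list alone), with Prom1 at -2.91 and Sox18 at -1.71 (adjusted p = 4.15e-06, estimated 0.0363). Wnt genes were lower in 12 of 28 cases and higher in 4 (13 and 4 over the list alone), with Wnt5a at -2.24 and Lef1 at -1.79 (adjusted p = 8.61e-06, estimated 0.0209).

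Among the other lists, mature adipocyte genes were higher in Dlk1+ Sca1+ than in reticular cells in 4 of 16 cases and lower in none (4 over the list alone), with Cd36, Fabp4, Car3 (2.04) and Lpl (1.43), at adjusted p = 0.00207 (adjusted p = 0.0898 with an estimated correlation). Skeletal muscle genes were lower in 5 of 13 cases and higher in none (5 over the list alone), with Acta1 at -1.38, at adjusted p = 0.00214 (adjusted p = 0.127 with an estimated correlation). Pericyte and smooth muscle genes were lower in 3 of 13 cases and higher in none (4 over the list alone), with Myl9 at -1.06, at adjusted p = 3.18e-05 (adjusted p = 0.0533 with an estimated correlation). Genes of adipogenic commitment moved both ways, with Pparg higher by 1.85 and Cd24a at -1.55 (adjusted p = 0.783). In all, 1441 genes passed (8.43%), 694 higher and 747 lower, and 14 lists passed. The direction of the count depended on scaling, since with arrays centred on their medians 894 of 1519 genes were higher and 625 lower. Without animals 1, 2 and 3 the count was 880, 668 and 498, and without Dlk1+ Sca1+ replicate 3 it was 908.

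Dlk1− Sca1+ cells differed from reticular cells in more genes than Dlk1+ Sca1+ cells did. Cd36 was higher by 4.02 ± 0.18, a 16.2-fold difference, Adamts18 by 3.42 ± 0.19, the prostaglandin transporter gene Slco2a1 by 3.11 ± 0.14, Cyp1b1 by 3.06 ± 0.13 and Tek by 2.90 ± 0.11. Ugt1a9 and Ugt1a6a were higher by 3.54 ± 0.14 and 3.48 ± 0.13. Thbs4 was at -5.29 ± 0.16, a 39.2-fold difference, Angptl1 at -4.17 ± 0.13, the homeobox gene Meox2 at -3.24 ± 0.17, Mgp at -3.05 ± 0.14 and Loxl3, which belongs to the enzymes that cross-link collagen, at -3.03 ± 0.11.

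Fibrillar collagen genes and their modifiers were lower in Dlk1− Sca1+ than in reticular cells in 14 of 27 cases and higher in 2 (14 and 3 over the list alone), with Col14a1 at -1.73 beside Loxl3, at adjusted p = 2.39e-06 (adjusted p = 0.268 with an estimated correlation). Elastic fibre genes were lower in 9 of 15 cases and higher in 3 (9 and 3 over the list alone), with Fbln1 at -1.16, though Efemp1 was higher by 2.70, at adjusted p = 0.00744 (adjusted p = 0.166 with an estimated correlation). Genes of TGF-beta and BMP signalling were lower in 11 of 26 cases and higher in 1 (13 and 1 over the list alone), with Inhba at -2.11 and Bmp4 at -1.72, at adjusted p = 0.00017 (adjusted p = 0.0816 with an estimated correlation). Mature adipocyte genes were higher in 6 of 16 cases and lower in 1 (7 and 1 over the list alone), with Fabp4 at 2.39, Car3 at 1.86 and Lpl at 1.41, at adjusted p = 0.00143 (adjusted p = 0.0825 with an estimated correlation), and Pparg was higher by 2.43. Skeletal muscle genes were lower in 6 of 13 cases and higher in none (6 over the list alone), with Acta1 at -2.54, at adjusted p = 0.000206 (adjusted p = 0.0825 with an estimated correlation). Pericyte and smooth muscle genes were lower in 5 of 13 cases and higher in none (5 over the list alone), with Kcnj8 at -2.56, at adjusted p = 0.00134 (adjusted p = 0.0825 with an estimated correlation). In all, 3104 genes passed (18.2%), 1600 higher and 1504 lower, and 13 lists passed. With arrays centred on their medians 1842 were higher and 1280 lower. Without animal 2 and animal 3 the count of genes was 1780 and 1681.

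Between the 2 Sca1+ populations, Dlk1− Sca1+ cells had higher Sema3g (2.57 ± 0.14, 5.95-fold), Kif26b (2.40 ± 0.17), Aqp1 (2.13 ± 0.25), Ugt1a9 (2.07 ± 0.14) and Adamts18 (1.95 ± 0.19). Sod3, which encodes the extracellular superoxide dismutase, was at -3.35 ± 0.15, a 10.2-fold difference. Angptl1 was at -3.12 ± 0.13, Thbs4 at -2.57 ± 0.16, Loxl3 at -2.53 ± 0.11, Meox2 at -2.45 ± 0.17 and the potassium channel gene Kcnj8 at -2.42 ± 0.16.

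No list passed with an estimated correlation in Dlk1− Sca1+ against Dlk1+ Sca1+ cells. Fibrillar collagen genes and their modifiers were lower in 9 of 27 cases and higher in 2 (12 and 2 over the list alone), with Loxl3 and Col14a1 (-1.37) lower and Col11a1 (1.97) higher, at adjusted p = 9.15e-08 (adjusted p = 0.215 with an estimated correlation). Elastic fibre genes were lower in 7 of 15 cases and higher in 1 (9 and 2 over the list alone), with Fbn2 at -0.76, at adjusted p = 0.000235 (adjusted p = 0.0825 with an estimated correlation). Chemokine, cytokine and complement genes were lower in 5 of 24 cases and higher in 1 (7 and 2 over the list alone), with C4b at -1.45 and C1s1 at -1.03, at adjusted p = 0.00473 (adjusted p = 0.256 with an estimated correlation). Papillary list genes were higher in 4 of 18 cases and lower in 1 (6 and 1 over the list alone), with Wif1 at 1.78 and Entpd1 at 1.03, at adjusted p = 0.00473 (adjusted p = 0.108 with an estimated correlation). Mature adipocyte genes did not pass (adjusted p = 0.232). In all, 1258 genes passed (7.36%), 552 higher and 706 lower, or 1897 with the animal as a block, and 14 lists passed. Without animals 1, 2 and 3 the count of genes was 636, 633 and 532.

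Along the genes that separate reticular from Dlk1− Sca1+ cells, Dlk1+ Sca1+ cells lay between the 2. On a scale from 0 for reticular to 1 for Dlk1− Sca1+, over genes chosen in the other 2 animals, their position was 0.524, 0.57 and 0.529 in the 3 animals (2401, 2047 and 1786 genes), with a mean of 0.541 ± 0.0256 (SD, n = 3) and no test. No other population was placed on this scale, and one unrelated to both could also fall near its middle. The value alone therefore does not show an intermediate population. The position between the 2 also does not hold on other axes. On the first principal component the Dlk1+ Sca1+ arrays (23.38 to 26.35) lay outside both the reticular (9.35 to 13.86) and the Dlk1− Sca1+ arrays (16.25 to 18.28). Trps1 and Entpd1 were lowest in Dlk1+ Sca1+ cells, at 6.82 ± 0.27 and 5.53 ± 0.11, against 9.59 ± 0.24 and 7.62 ± 0.21 in reticular and 8.32 ± 0.23 and 6.56 ± 0.15 in Dlk1− Sca1+ cells.

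Markers of other cell types were measured in each array. The mean of the keratinocyte list was 9.28 in the Dlk1− Sca1+ array of animal 1, 7.08 and 7.10 in the other 2 arrays of that population, and 6.30 to 7.79 elsewhere. Krt5 was at 12.10 in that array. It was also at 10.92, 11.09 and 10.68 in the papillary, reticular and Dlk1+ Sca1+ arrays of animal 1. In the Dlk1+ Sca1+ array of animal 2 it was at 10.94, and at 8.18 to 9.86 elsewhere. Keratinocyte genes were higher in Dlk1− Sca1+ than in reticular cells in 2 of 15 cases and lower in none (2 over the list alone), at adjusted p = 0.014 (adjusted p = 0.625 with an estimated correlation). They were lower in papillary than in Dlk1− Sca1+ cells in 3 of 15 cases and higher in none (3 over the list alone), at adjusted p = 0.0146 (adjusted p = 0.625 with an estimated correlation). Endothelial genes passed between the Sca1+ populations at adjusted p = 0.0461 (adjusted p = 0.379 with an estimated correlation, and 0.545 and 0.203 without animal 2 and animal 3), with the list as a whole lower in Dlk1− Sca1+ cells. Of its 16 genes 1 was higher there and none lower (1 and 1 over the list alone). The skeletal muscle list was at 6.08 to 6.25 in reticular, 5.82 to 5.88 in Dlk1+ Sca1+, 5.51 to 5.65 in Dlk1− Sca1+ and 5.56 to 5.58 in papillary arrays. The pericyte and smooth muscle list was at 7.41 to 7.90 in reticular and 6.51 to 6.54 in papillary arrays, and the pericyte marker Rgs5 reached 9.52 in the reticular and 8.98 in the Dlk1+ Sca1+ array of animal 2. Immediate early and dissociation stress genes, which rise when tissue is taken apart, were lower in papillary cells than in each other population. Against reticular cells 11 of 19 were lower and none higher (13 over the list alone, adjusted p = 4.15e-06, and adjusted p = 0.194 with an estimated correlation). Against Dlk1+ Sca1+ cells 13 were lower and none higher (13 over the list alone, adjusted p = 1.66e-07, and adjusted p = 0.143 with an estimated correlation). Against Dlk1− Sca1+ cells 12 were lower and none higher (12 over the list alone, adjusted p = 1.05e-05, and adjusted p = 0.214 with an estimated correlation). Nr4a1 was at 10.04 ± 0.22 in papillary cells and at 11.22 ± 0.05, 11.19 ± 0.08 and 11.17 ± 0.11 in reticular, Dlk1+ Sca1+ and Dlk1− Sca1+ cells, while Fos was near the top of the scale in all 12 arrays (12.35 to 12.58). These genes moved in the same direction as the chemokine, cytokine and complement genes, and these arrays do not separate handling from the state of the cells in the skin.

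**Figure D5:**
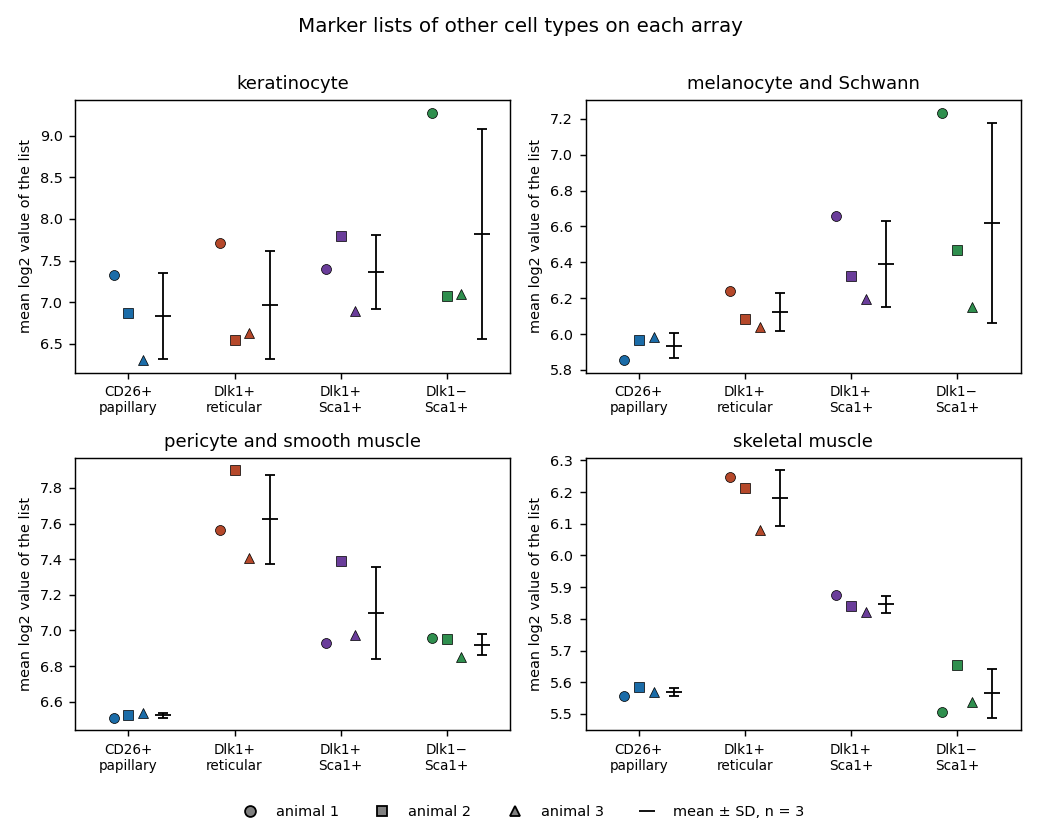
Mean log2 level of the keratinocyte, melanocyte and Schwann, pericyte and smooth muscle, and skeletal muscle lists in each array.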

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

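This part holds 1 result, which comes from probe sets outside the gene counts, and no test in it was chosen after the result was seen. Of the 16139 probe sets that were not controls and had no single gene name, 4705 (29.2%) passed the F-test among the 4 populations, against 6100 of 17097 named genes (35.7%). Between papillary and Dlk1+ Sca1+ arrays 4117 of them passed, and between the 2 Sca1+ populations 705. These probe sets respond to the populations, and which transcripts they measure was not analysed here.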

How the results depend on the processing

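The covariate of keratinocyte markers and the joint omission of 3 arrays were chosen only after the results were seen. Counts of probe sets, with every probe set tested, were 11567, 12341 and 11304 for papillary against reticular, Dlk1+ Sca1+ and Dlk1− Sca1+ cells, 3031 and 6873 for Dlk1+ Sca1+ and Dlk1− Sca1+ against reticular, 2678 between the Sca1+ populations and 14983 by the F-test. Those highest in papillary, reticular, Dlk1+ Sca1+ and Dlk1− Sca1+ were 3621, 679, 171 and 564. In the same orders, a 2-fold minimum left 951, 1123, 1060, 234, 464 and 197 genes, and 295, 45, 13 and 31 highest genes.

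With the animal as a block, 1897 genes passed between the Sca1+ populations, and 169 and 424 were highest in Dlk1+ Sca1+ and Dlk1− Sca1+ cells. Among the results named by the rule, the block ended the calls of Mrc1 (adjusted p = 0.0597) and Hba-a1 (0.0646) in papillary against Dlk1+ Sca1+ and of dermal papilla genes between the Sca1+ populations (0.128). It brought keratinocyte genes there from 0.0555 to 0.0362, and the other calls it added are given with the results. Without the Dlk1− Sca1+ array of animal 1 and the reticular and Dlk1+ Sca1+ arrays of animal 2, counts were 927 for Dlk1+ Sca1+ against reticular, 1991 for Dlk1− Sca1+ against reticular, 775 between the Sca1+ populations, and 178 and 157 highest in reticular and Dlk1− Sca1+.

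Lists passing with an estimated correlation were 1, 3, 3, 5, 0 and 0 in the order of the comparisons above, and fry called 19 in papillary against Dlk1− Sca1+, where camera called 12. The direction of the keratinocyte list in Dlk1− Sca1+ against reticular turned with the covariate (adjusted p = 0.711) and without the 3 arrays (0.573). The covariate was the mean of this same list, so the loss of the call with it was built in. The 3 arrays were chosen for high markers and include the one with the highest keratinocyte mean. These are the 2 turned list values counted below. Ramp2 in papillary against Dlk1− Sca1+ turned from 0.17 to -0.18 with the mean of its probe sets (adjusted p = 0.0292).

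Leave-one-out ranges of gene counts, over single arrays and animals, were 3243 to 4609, 3442 to 4327, 3120 to 4171, 498 to 1138, 1681 to 2864 and 532 to 1180 genes, 3949 to 6038 by the F-test, and 912 to 1332, 119 to 325, 26 to 100 and 101 to 287 highest genes. Over animals alone, lists ranged over 18 to 19, 16 to 17, 12 to 16, 14 to 15, 13 to 15 and 10 to 15, and the position over 0.526 to 0.55. Of 577 called results of named genes, 454 passed in all alternatives run, and of 87 list calls 12 did. Over the alternatives, 10298 gene values kept call and direction, 619 lost the call and 1 turned, and for lists 927, 115 and 2 did.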

Other observations

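The 3 tests on the Dlk1 transcript, the splits and assignments of names within animals and the random lists for the first muscle list and its brighter members were chosen only after the result was seen, and the gene-by-gene Dlk1 test was added after the share test had come out. Part of a list of imprinted genes moved with the Dlk1 gate. A list of 25 measured imprinted genes other than Dlk1 was written before it was tested. In Dlk1− Sca1+ against Dlk1+ Sca1+ cells 11 of them were lower, 1 was higher and 13 did not pass, with a median of -0.36. Igf2 was also in the reticular list and among the genes called in this comparison, so it was not new here. The imprinted list had an adjusted p of 1.82e-09 in camera, and 0.11 with an estimated correlation. Igf2 fell by 0.81, Zdbf2 by 1.16 and the non-coding Meg3, Rian and Mirg of the Dlk1 locus by 0.42, 0.55 and 0.94, while Rasgrf1 was higher by 0.47 and Cdkn1c (0.08), Peg3 (-0.15) and Slc38a4 (-0.30) did not pass. The list was also lower in Dlk1− Sca1+ than in reticular cells (12 lower, 1 higher, 1.26e-07), in papillary than in reticular (15 lower, 1 higher, 3.24e-08) and in papillary than in Dlk1+ Sca1+ cells (13 lower, 1 higher, 3.49e-07). All 4 calls end with an estimated correlation (0.11 in each), so a shared regulation of this group may be proposed but was not shown.

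Conjugating enzymes of the Ugt1a locus were high in Dlk1− Sca1+ cells. A wider electrophile and xenobiotic list of 36 genes, without the genes already seen, had 4 higher and 3 lower in Dlk1− Sca1+ against Dlk1+ Sca1+ cells (adjusted p = 0.907). The test gave no sign of a wider response between these 2 populations. Against reticular cells the list was higher in Dlk1+ Sca1+ (9 higher, 1 lower, adjusted p = 0.00356) and in Dlk1− Sca1+ (10 higher, 5 lower, 0.038), and it was lower in papillary than in Dlk1− Sca1+ cells (14 lower, 5 higher, 0.0116). These calls end with an estimated correlation (0.11, 0.216 and 0.147).

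Keratinocyte markers were highest in the Dlk1− Sca1+ array of animal 1, although the gate removed EpCam positive cells. Krt5 was also high in the other arrays of animal 1 and the Dlk1+ Sca1+ array of animal 2, which were not tested. A second keratinocyte list of 37 measured genes, not looked at before, had a median of 1.1 log2 above the other 2 arrays of the population, with 21 members higher by over 0.5, where the highest of 1000 random lists matched on level reached 0.02. A programme shared by all Dlk1− Sca1+ arrays is argued against, since the lower median in animals 2 and 3 against reticular was -0.02. Keratinocyte RNA in that library is the candidate explanation that stays open. The means of the melanocyte and Schwann list (7.24) and the mast cell list (5.75) were highest in that array as well.

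Skeletal muscle transcripts were higher in reticular than in papillary arrays. A second list of 31 measured muscle fibre genes had a median of 0.11, above the central 95% of random lists (-0.04 to 0.08), and a higher mean in reticular cells in all 3 animals (0.203, 0.259 and 0.239). Of its genes 7 were called higher in reticular cells and 0 lower. Muscle fibre RNA in the reticular libraries may be the source, although the layer under the dermis was removed and the sort took cells with Pdgfra and CD34, steps that should leave fibres out. Expression in reticular cells themselves was not tested. A general shift of dim probe sets stays open as well. The 5 members of the first list past the dim filter (Acta1, Tnnc2, Mylpf, Ckm and Myod1) had a median of 1.11. It lay above all random lists matched on level (highest 0.893), and the list passed at 0.00203 with dim genes left out. The filter used the mean over all arrays, so the change itself helped decide which members passed. In papillary cells Acta1 (5.12, against 8.16 in reticular) and Tnnc2 (6.02, against 8.71) were under the cut of 6.28. Mylpf and Ckm were above it there, both at 6.43. These tests therefore do not decide on the shift for these members. For the dimmer members the shift cannot be told apart either. The second list sat at percentile 99.9 with the highest random list also at 0.11. The whole first list's median of 0.213 lay under the highest of its own random lists (0.217).

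The Dlk1 transcript in Dlk1− Sca1+ cells was at 36% of its level in Dlk1+ Sca1+ cells. If Dlk1+ Sca1+ cells in the gate were its source at that share, all transcripts would be at 36% or above. By the first test 15 of 705 genes called lower, or 2.13%, had an upper 95% bound under that ratio, within the 2.5% it allowed, which is what the explanation needs. That allowance assumes each gene to sit exactly at the Dlk1 ratio, and in the later gene-by-gene test 7 genes lay under the ratio, led by Sod3 (9.83%, upper bound 12.4%) and Angptl1 (11.5%), which argues against cells at that share. A smaller share with the Dlk1 signal compressed near the top of the scale cannot be told apart, since 0.0289% of probe sets were as bright as Dlk1 in the Dlk1+ arrays, and transcription of Dlk1 in cells without the surface protein was not tested.

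Other splits of the 12 arrays, of which 100 were drawn with the real one included, were run for the population counts. By the F-test the real count was 6100 and the highest other 3378, and for genes highest in papillary cells 1363 and 1167, with 1 split, the real one, giving as many in each case. In 5 splits the papillary arrays fell together, the real one included, and in the 95 that spread them the highest F count was 487. These splits ignore the shared animals and mostly record where the papillary arrays fell, so they exclude chance at most for labels exchangeable over all 12 arrays and test nothing among the other 3 populations. For genes highest in reticular (317), Dlk1+ Sca1+ (99) and Dlk1− Sca1+ cells (264), 2, 2 and 1 splits gave as many, with highest others of 1198, 1204 and 32. The first 2 are several times the real counts and point to the structure set by the papillary arrays, so this null decides nothing for these counts.

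A test of those 3 counts held the papillary arrays and exchanged the other labels within animals, which makes 36 splits. With the labels of animal 1 fixed, 1 split, the real one, gave as many genes in each case, and the real and highest other counts were 317 and 218 for reticular, 99 and 18 for Dlk1+ Sca1+ and 264 and 177 for Dlk1− Sca1+ cells. With all 216 assignments of the 3 names counted, 2 gave as many for reticular and 4 for Dlk1− Sca1+, with highest others of 264 and 317. These others are the real counts of Dlk1− Sca1+ and reticular cells under exchanged names. How many assignments gave as many thus followed partly from the order of the 3 real counts, so chance labels are not called excluded by it. For Dlk1+ Sca1+ 18 of the 216 gave as many, with 317 as the highest other. Apart from its own arrays, these assignments put all reticular or all Dlk1− Sca1+ arrays under the Dlk1+ Sca1+ name, with counts of 159 to 317. They record the genes of those populations, so this null decides nothing for the count of 99. With the labels of animal 1 fixed, the highest other count under that name was 18.

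The 6 arrays of a comparison have 10 splits, too few for a share under 0.05. The other splits mixed arrays of both populations unevenly and kept part of their difference, so their counts do not measure chance. The real counts of genes were 4702, 4787 and 4508 for papillary against reticular, Dlk1+ Sca1+ and Dlk1− Sca1+, 1441 and 3104 for Dlk1+ Sca1+ and Dlk1− Sca1+ against reticular and 1258 between the Sca1+ populations, and the highest others were 0, 0, 0, 2, 0 and 0. For lists the real counts were 18, 16, 12, 14, 13 and 14 and the highest others 14, 12, 12, 11, 14 and 12, with 1, 1, 2, 1, 2 and 1 splits giving as many. The 3 other splits that part all pairs of an animal, as the real one does, gave 0 genes and up to 10, 12, 12, 11, 14 and 12 lists. The 6 splits that part 1 pair gave up to 0, 0, 0, 2, 0 and 0 genes and 14, 12, 10, 8, 11 and 9 lists.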
